A study of Homo sapiens with 20 samples.

How the data were processed

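RNA of primary human mesangial cells was measured by bulk RNA sequencing in 20 libraries of 4 groups, 5 libraries each: cells given 50 µg of NETs for 72 h, cells given 5 µg of recombinant citH3 for 48 h, and controls of either duration. Per the labels' protocols, the libraries were made with a directional kit and sequenced on a NovaSeq X Plus. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0, STAR 2.7.8a, Partek and DESeq2, with the hg38 build, and no role or order is given for them. The gene annotation, the strand setting of the counting and any filter before deposit are not given in the sources used here, so genes that overlap others on the opposite strand are uncertain. The volume in which each amount was given, and so the concentration, is not used here.

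The values came as 2 tables of raw values per gene and library, each for its own comparison. The NETs table holds estimated counts, as the authors deposited them: 46.7% of its values are not whole, and they were rounded to whole numbers before any test. The citH3 table holds whole-number counts, as the authors deposited them, and all 47 of its values of 1e+06 or more carry 3 significant digits. The test plan had allowed for either form. The tables list 28920 and 30522 genes, of which 27986 are shared; 7005 and 7789 carry an identifier without a symbol. Of the identifiers, 93.2% and 92.9% were found in GENCODE release 29, from which hg38 coordinates, strand and gene type were taken; SOD2 has an identifier outside it and is given without coordinates. Totals per library were 73868400 to 94387700 in the NETs table and 42319800 to 80210800 in the citH3 table. At these depths a gene at 1 CPM has at least 42.3 counts. The tables were tested separately, except in the fits of all 20 libraries described below. Levels were not compared between them except where 72 h and 48 h controls are set side by side and named.

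Each stimulus was compared with the 5 controls of its own duration by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided), with trimmed-mean (TMM) factors and filterByExpr at its minimum count of 10 and minimum total of 15. Adjusted p-values follow Benjamini and Hochberg over the genes kept, with a threshold of 0.05. The difference of the effects was tested as a contrast of 4 group means in 1 fit of all 20 libraries. Tables of the calls were compared by the overlap that independent lists would have, from the calls of each among the genes tested in both, and by Fisher's exact test. CPM values use TMM-adjusted totals of the same table, those beside the difference of effects use factors from all 20 libraries, and sums of transcripts and the level of MPO use library totals. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, over lists of at least 5 tested genes, and again with an estimated correlation and with fry. Sums of marker transcripts per library were compared by two-sided exact permutation tests. The genes in a list that pass are also counted after adjustment over the list alone.

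The design, the tests, 28 gene lists and the alternatives, except those named below as later, were fixed before the data were examined. The lists cover cytokines and chemokines, NF-kappaB feedback and adhesion, type I interferon response, antigen presentation, extracellular matrix, proteases and inhibitors, contractile genes, mesangial and pericyte markers, proliferation, hypoxia, the unfolded protein response, NRF2 targets, metallothioneins, complement, innate receptors, cholesterol synthesis, p53 targets, immediate early genes, TGF-beta targets and mitochondrial transcripts, and markers of neutrophils, monocytes, lymphocytes, endothelium, podocytes, tubules and blood cells, with olfactory receptors as a check for genomic DNA. The genes named were the 6 with the largest rise and the 6 with the largest fall among those past the threshold, at a mean of at least 2 CPM in the higher group and with no overlap between the groups, and the member of each list with the smallest p. For the difference of effects they were the 5 largest in each direction at 2 CPM or more in at least 1 group. Clone names, pseudogenes and genes without a symbol were left out. Some genes that these rules select are not reported here. Further members named as examples of a list were chosen after their values were seen: in the NETs comparison ACTA2, MYH11, LAMC1, DCN, NOTCH3, THY1, IL6, CXCL8, MX1, COL1A1, TFPI, NFKBIA and ATF3, and in the citH3 comparison the other members named beside the leading gene of each list. The examples FDPS, ATF4, C5, KRT19, MCM5, MT2A, MKI67 and CCL2 were dropped from the NETs comparison after fits without single libraries. Their calls were lost or gained there. MYH11 was kept although its call was also lost in such fits. The other examples kept are therefore steadier than the lists they stand for. The counts per list include the dropped genes.

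The steps were tested on simulated counts drawn from the means, totals and spread of the real libraries, with 200 genes changed in each of 5 draws. This test was extended from 1 to 5 draws after the first gave 11% false calls for the citH3 comparison. The NETs comparison recovered 61.2%, 76.4% and 93.0% of genes changed 1.5-fold, 2-fold and 4-fold, with 4.34% of calls false (2.37% to 6.40%), over 18067 genes. The citH3 comparison recovered 71.3%, 82.7% and 95.2%, with 7.72% of calls false (5.79% to 11%), over 17978 genes. The difference of effects recovered 58.5%, 78.2% and 93.2%, with 6.57% of calls false (5.13% to 8.73%), over 17456 genes. In the simulated NETs comparison camera called the raised list of 25 and 0 others. Each gene was drawn on its own, so this run cannot show how often camera calls lists of genes that vary together.

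The counts of genes called and the named genes were recomputed with DESeq2 1.42.0, limma-voom, other size factors, library totals only, other filters on low counts and the replicate number as a block, and for each stimulus with all 20 libraries in 1 fit. The overlap counts were recomputed with DESeq2, library totals only, the filter at 1 CPM in 5 libraries, the block and a stricter threshold, and the gene lists with library totals only, that filter, the block, an estimated correlation and fry. For all of these and for the marker sums each library was left out in turn. Voom with library quality weights, the TMM-adjusted totals and left-out libraries for the marker sums, all settings for genes called in opposite directions, and the marker sums without their leading member were added after the data were seen. Figures were drawn with matplotlib 3.10.9. Transcripts of the Y chromosome and of X inactivation were not reported. No column of another sample was present, so 0 were left out.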

Results

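Primary human mesangial cells were cultured with or without a stimulus related to neutrophils, and their RNA was sequenced. Mesangial cells are the contractile, matrix-producing cells between the capillaries of the kidney glomerulus. Neutrophil extracellular traps (NETs) are webs of chromatin and granule proteins that neutrophils release. Citrullinated histone H3 (citH3) is a histone found in such traps, in which arginine has been converted to citrulline. By its title the series concerns signalling between neutrophils and mesangial cells in lupus nephritis. Cells received 50 µg of NETs for 72 h (5 libraries) or 5 µg of recombinant citH3 for 48 h (5 libraries), and each stimulus had 5 control libraries of its own duration. Total counts ranged from 73868400 to 94387700 per library at 72 h and from 42319800 to 80210800 at 48 h. The labels do not say whether replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. All 40 pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom 4.14 to 132), and each library was counted as 1 replicate. Levels are given as CPM, counts scaled to a library total of 1e+06, in mean ± SD, and log2 fold changes as estimate ± standard error, with n = 5 in each group.

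The comparison at 72 h asked how mesangial cells respond to NETs. Leading genes in either comparison were taken from genes with a symbol past the threshold, at a mean of 2 CPM or more in the higher group and without overlap between the groups. SLC14A1, which encodes a urea transporter, rose from 0.970 ± 0.260 to 4.99 ± 1.46 CPM, a log2 fold change of 2.36 ± 0.24 (edgeR adjusted p = 0.000559). PADI2, which encodes an enzyme that converts protein arginine to citrulline, rose from 17.9 ± 16.3 to 66.3 ± 18.5 CPM, by 1.89 ± 0.52 (edgeR adjusted p = 0.0384). Among genes that met this rule the largest fall was in ADORA2A, the gene of an adenosine receptor, from 12.6 ± 7.63 to 1.02 ± 0.725 CPM, or -3.63 ± 0.57 (edgeR adjusted p = 0.00319). RCAN1, an inhibitor of calcineurin, fell from 593 ± 342 to 152 ± 25.5 CPM (-1.96 ± 0.37). Further leading rises were in MXRA5 (1.59 ± 0.27), PRKG2, a cGMP-dependent protein kinase (1.55 ± 0.24), and SCG2, a secretory granule protein (1.37 ± 0.16). The other leading falls were in CCDC102B (-2.61 ± 0.38), C11orf96 (-2.43 ± 0.46), ENPP2, which encodes the enzyme autotaxin (-1.96 ± 0.34), and SH2D3C (-1.91 ± 0.30). The call of PADI2 was lost without control 1, 3 or 5 or NETs 2, 3, 4 or 5, each left out in turn; the adjusted p in these edgeR fits ranged from 0.0503 without control 1 to 0.101 without control 3.

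In hg38, SLC14A1 (ENSG00000141469) lies on chromosome 18 from 45687025 to 45752520, on the plus strand. PADI2 (ENSG00000117115) lies on chromosome 1 from 17066761 to 17119435, on the minus strand. ADORA2A (ENSG00000128271) lies on chromosome 22 from 24417879 to 24442360, on the plus strand. RCAN1 (ENSG00000159200) lies on chromosome 21 from 34513142 to 34615142, on the minus strand. All 4 are annotated as protein-coding genes, and each value is 1 count per gene and library.

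Of 18319 genes tested after NETs, 1980 passed, of which 646 were higher and 1334 lower. At least a 2-fold change was reached by 58 of the higher and 153 of the lower genes. With library totals in place of trimmed-mean factors the split turned to 1526 higher and 978 lower. The 72 h controls did not form 1 group: on the first principal component, 36.0% of the variance, controls 1, 3 and 5 lay between -42.5 and -37.0, control 2 at -0.92 and control 4 at 15. The NETs libraries lay between 4.23 and 33.6 on the same component. The median coefficient of variation of genes at 10 CPM or more was 7.80% in the 72 h controls and 5.26% in the NETs libraries. Without control 4 the test called 4692 genes, and it called 809 without control 3, 839 without control 5, 824 without NETs 3, 891 without NETs 4 and 837 without NETs 5. DESeq2 called 3433 genes, a fit of all 20 libraries 3997, and limma-voom with library quality weights, an alternative chosen after the data were seen, 7576.

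**Figure D1:**
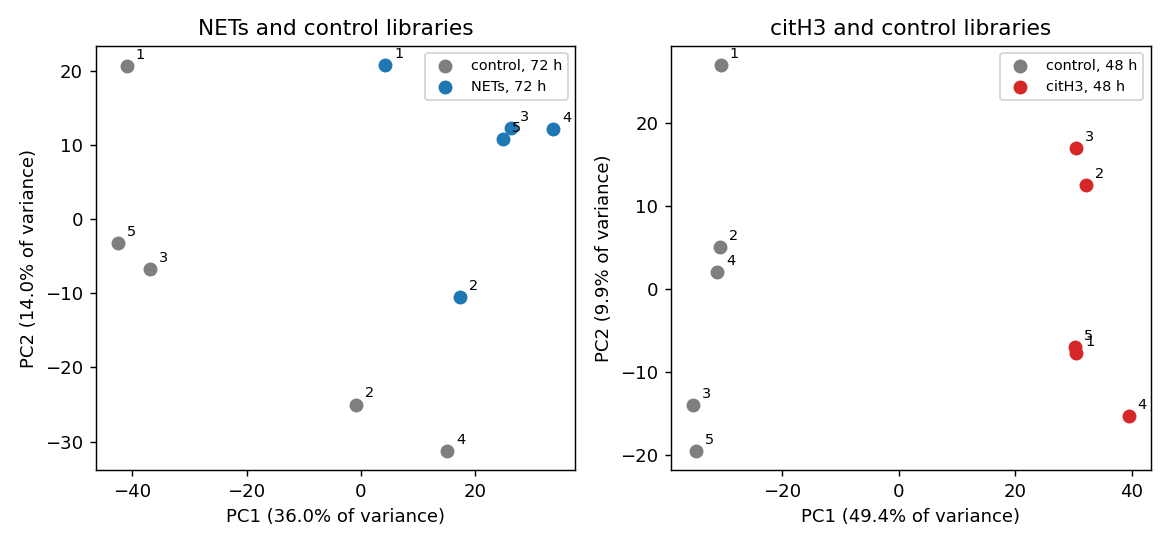
First 2 principal components of log2 CPM for the 72 h libraries (left) and the 48 h libraries (right), each point a library labelled with its replicate number and the axes giving the share of variance. At 72 h controls 2 and 4 lie at -0.92 and 15 on PC1, away from the other controls at -42.5 to -37.0, while at 48 h all citH3 libraries lie above 30.2 and all controls at -30.6 or below.

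Of 16 genes of the contractile apparatus tested after NETs, 9 fell and 0 rose (10 and 0 adjusted over the list alone). ACTG2, a smooth muscle actin, fell from 174 ± 22 to 113 ± 9.83 CPM, and ACTA2, the actin commonly used to mark myofibroblasts, fell by 0.34 ± 0.07 on the log2 scale. MYH11, the smooth muscle myosin heavy chain, fell from 28.8 ± 11 to 9.19 ± 7.32 CPM (-1.65 ± 0.43). That call was lost without control 1, 3 or 5 or NETs 2, 3, 4 or 5, at edgeR adjusted p from 0.0550 to 0.0881, and without NETs 1 the fold was -2.26. The list stood apart from other genes by camera at adjusted p = 1.32e-05 with a preset correlation, and at adjusted p = 0.433 with an estimated correlation. Of 15 mesangial and pericyte markers tested, 5 fell and 0 rose (8 fell when adjusted over the list alone). PDGFRB, the receptor for platelet-derived growth factor, fell from 694 ± 60.8 to 489 ± 29.4 CPM, THY1 changed by -0.41 ± 0.07 and NOTCH3 by -0.80 ± 0.16. Camera gave this list an adjusted p = 0.00166, and an adjusted p = 0.433 with an estimated correlation. For MYH11 and NOTCH3 the values of the NETs and control libraries overlapped, and controls 2 and 4 lay toward the NETs libraries on the first principal component, as given above.

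Of 18 genes of cholesterol synthesis, 5 fell and 0 rose, and 13 fell when adjusted over the list alone. SREBF2, the transcription factor that drives the pathway, fell from 177 ± 14.3 to 133 ± 20.2 CPM (-0.42 ± 0.10). Its call was lost without control 3 or NETs 3, 4 or 5, at edgeR adjusted p from 0.0514 to 0.0534. Camera gave the list an adjusted p = 1.35e-05, and an adjusted p = 0.601 with an estimated correlation. Of 30 proliferation genes 5 rose and 0 fell (12 and 1 adjusted over the list alone). MCM4, part of the helicase that opens replication origins, rose from 9.54 ± 1.69 to 14.2 ± 1.65 CPM. Camera gave the list an adjusted p of 6.15e-05, and adjusted p = 0.633 with an estimated correlation. Of 6 metallothionein and zinc genes, 3 rose and 0 fell (4 adjusted over the list alone). MT1E rose from 7.48 ± 2.77 to 14.5 ± 2.87 CPM, a call lost without control 3, NETs 3 or NETs 4 at edgeR adjusted p from 0.0538 to 0.0568. The camera adjusted p of this list was 0.0207, and adjusted p = 0.433 with an estimated correlation.

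The calls in the inflammatory lists after NETs stand beside 1980 calls among all 18319 genes tested (10.8%). Of 20 genes of NF-kappaB feedback and adhesion, 3 fell and 0 rose, in the count over all genes and adjusted over the list alone. ICAM1, an adhesion molecule for leukocytes, fell from 125 ± 10.3 to 89.7 ± 2.25 CPM, and NFKBIA, the inhibitor of NF-kappaB, by 0.36 ± 0.08 on the log2 scale. By camera the list had an adjusted p of 0.0397, and adjusted p = 0.433 with an estimated correlation. The camera call was lost without control 2 (adjusted p = 0.0996), control 4 (0.163), NETs 1 (0.126) or NETs 5 (0.0712). Of 21 cytokines and chemokines, 1 rose and 2 fell (1 and 3 adjusted over the list alone). CXCL12, a chemokine of stromal cells, rose from 95 ± 17.9 to 207 ± 33.9 CPM. CXCL8 was at 0.985 ± 0.173 CPM in controls and 0.773 ± 0.217 with NETs, and IL6 at 4.76 ± 1.2 and 5.88 ± 0.820 CPM; neither passed. Of 30 interferon-response genes tested 0 rose and 2 fell, with RIGI, a sensor of viral RNA, at -0.42 ± 0.09 and the same counts adjusted over the list alone. MX1 had a log2 fold change of -0.10 ± 0.62 and did not pass; without control 2 it was 1.12, again without passing. Without control 2 the interferon list was called by camera as higher (adjusted p = 0.0026). Of 19 antigen presentation genes 0 rose and 3 fell (1 and 3 adjusted over the list alone), led by TAP1, a peptide transporter (-0.25 ± 0.05). Of 17 innate receptors and inflammasome genes, NLRP1 alone passed, at -0.47 ± 0.07 (1 adjusted over the list alone). With all libraries camera did not call the cytokine, interferon, antigen presentation or innate receptor lists.

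Matrix genes went both ways. Of 32 extracellular matrix genes 2 rose and 5 fell (2 and 8 adjusted over the list alone). The laminin chains LAMA4 (-1.0 ± 0.11) and LAMC1 (-0.40 ± 0.06) were lower, the proteoglycan DCN was higher (0.43 ± 0.07), and the collagen COL1A1 did not pass (-0.04 ± 0.10). Of 20 matrix proteases and inhibitors 4 rose and 3 fell, with the same counts adjusted over the list alone, and MMP2, a gelatinase, rose from 787 ± 31.3 to 1048 ± 78.1 CPM. Of 21 complement and coagulation genes 5 rose and 2 fell (9 and 5 adjusted over the list alone), among them C1S (0.38 ± 0.07) and the coagulation inhibitor TFPI (-0.59 ± 0.12). Of 17 immediate early genes 2 rose and 5 fell (4 and 7 adjusted over the list alone), with DUSP1, a phosphatase of MAP kinases, at -0.89 ± 0.13 and ATF3 at -1.09 ± 0.18. Of 18 genes of the unfolded protein and amino acid response 0 rose and 5 fell (0 and 6 adjusted over the list alone), led by CHAC1 (-1.04 ± 0.22). Of 16 TGF-beta targets 3 rose and 2 fell (3 and 4 adjusted over the list alone), led by LTBP2 (0.45 ± 0.07). Of 15 NRF2 targets 1 rose and 2 fell, also when adjusted over the list alone, led by ME1 (-0.53 ± 0.10). Of 15 p53 and cell death genes 1 rose and 1 fell (2 and 4 adjusted over the list alone), led by PMAIP1 (-0.99 ± 0.11). Of 23 hypoxia and glycolysis genes ANKRD37 alone passed, at 0.76 ± 0.15 (1 rose and 2 fell adjusted over the list alone). Of 13 mitochondrially encoded transcripts 0 passed in either count, and MT-ND3 had the smallest p, at 0.12 ± 0.07 (edgeR adjusted p = 0.221). Camera called none of the lists in this paragraph with all libraries, and the unfolded protein list was called without NETs 4 (adjusted p = 0.0421). The median, mean and camera direction differed in sign for the antigen presentation, protease, hypoxia, TGF-beta, endothelial and tubular lists.

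Markers of other cell types were summed per library. Endothelial markers rose from 142 ± 8.71 to 182 ± 9.19 CPM and podocyte markers from 720 ± 110 to 883 ± 28.4. Tubular epithelial markers fell from 1923 ± 152 to 1534 ± 127 and neutrophil markers from 6.67 ± 0.170 to 5.60 ± 0.639 (each adjusted p = 0.0179, exact permutation test with Benjamini-Hochberg adjustment over 9 sums; the smallest unadjusted exact p this design can give is 0.00794). Single members carried most of these changes: TEK went from 68.5 to 101 CPM on the same library totals and the other endothelial markers together from 73.2 ± 4.73 to 80.8 ± 1.93. KRT18 went from 1809 to 1411 and the other tubular markers from 114 ± 16.2 to 123 ± 4.44, and without the member that changed most the podocyte markers went from 263 ± 45 to 285 ± 23.1. Monocyte and macrophage markers (3.26 ± 0.519 and 3.83 ± 0.292), lymphocyte markers (12.1 ± 1.95 and 12.2 ± 1.02), erythroid and platelet markers (0.178 ± 0.0491 and 0.176 ± 0.0526), mitochondrial transcripts and olfactory receptors (4.44 ± 0.556 and 3.98 ± 0.417) did not pass. The podocyte sum no longer passed with TMM-adjusted totals or without any 1 of the 5 NETs libraries (ratio of NETs to control 1.21 to 1.24), nor did the neutrophil sum without control 1, 3, 4 or 5 (ratio 0.835 to 0.847). Without control 2 the monocyte sum passed (ratio 1.24). By gene, 1 of 11 endothelial markers tested rose (TEK, 0.52 ± 0.08) and 1 fell, and 2 of 7 podocyte markers rose, among them PODXL (0.29 ± 0.07), whose call was lost without control 1 or 3 or NETs 3, 4 or 5 (edgeR adjusted p from 0.0508 to 0.0706). Of 9 tubular markers 2 rose and 1 fell (KRT18, a keratin, -0.39 ± 0.07). Adjusted over the list alone, 1 endothelial marker rose and 1 fell, 3 podocyte markers rose and 1 fell, and 2 tubular markers rose and 1 fell. Of 7 neutrophil markers 0 rose and 1 fell, in both counts. Of 5 monocyte, 3 lymphocyte and 1 platelet markers 0 passed in either count, with CD68 at 0.45 ± 0.23, CD4 at 0.15 ± 0.09 and ITGA2B at 0.10 ± 0.37.

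The comparison at 48 h asked how the cells respond to citH3. By the same rule for leading genes, the 6 with the largest rises encode chemokines, a complement component and an acute-phase protein. CXCL8, which attracts neutrophils, rose from 0.126 ± 0.0270 to 47.0 ± 17.4 CPM, a log2 fold change of 8.52 ± 0.31 (edgeR adjusted p = 1.93e-11). CXCL1, of the same chemokine family, rose from 0.260 ± 0.0457 to 69.9 ± 8.69 CPM (8.05 ± 0.12, edgeR adjusted p = 8.55e-16). The central complement component C3 rose from 0.770 ± 0.127 to 150 ± 19.5 CPM (7.60 ± 0.12). CCL5, a chemokine for T cells, rose by 6.39 ± 0.25, SAA1, an acute-phase protein, by 6.12 ± 0.30, and CXCL6 by 5.88 ± 0.10. The leading falls were in WNT2, a secreted signalling protein (-2.85 ± 0.17), and H19, an imprinted long non-coding RNA, which went from 504 ± 48.1 to 87.2 ± 29.7 CPM (-2.53 ± 0.21). KRT4 (-2.51 ± 0.22), CYP2W1 (-2.04 ± 0.18), SLC14A1 (-1.99 ± 0.14) and CPAMD8 (-1.98 ± 0.14) followed.

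In hg38, CXCL8 (ENSG00000169429) lies on chromosome 4 from 73740506 to 73743716 and CXCL1 (ENSG00000163739) on the same chromosome from 73869393 to 73871242, both on the plus strand. C3 (ENSG00000125730) lies on chromosome 19 from 6677704 to 6730562, on the minus strand. WNT2 (ENSG00000105989) lies on chromosome 7 from 117275451 to 117323289, and H19 (ENSG00000130600) on chromosome 11 from 1995176 to 2001470, both on the minus strand.

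Of 18226 genes tested, 5997 passed after citH3, of which 3139 were higher and 2858 lower. At least a 2-fold change was reached by 478 of the higher and 242 of the lower genes. With library totals in place of trimmed-mean factors the split was 2113 higher and 4455 lower. The first principal component, 49.4% of the variance, separated all citH3 libraries from all controls. On simulated counts with the spread of these libraries, 7.72% of the calls were false on average (5.79% to 11% over 5 draws), above the nominal 5%.

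**Figure D2:**
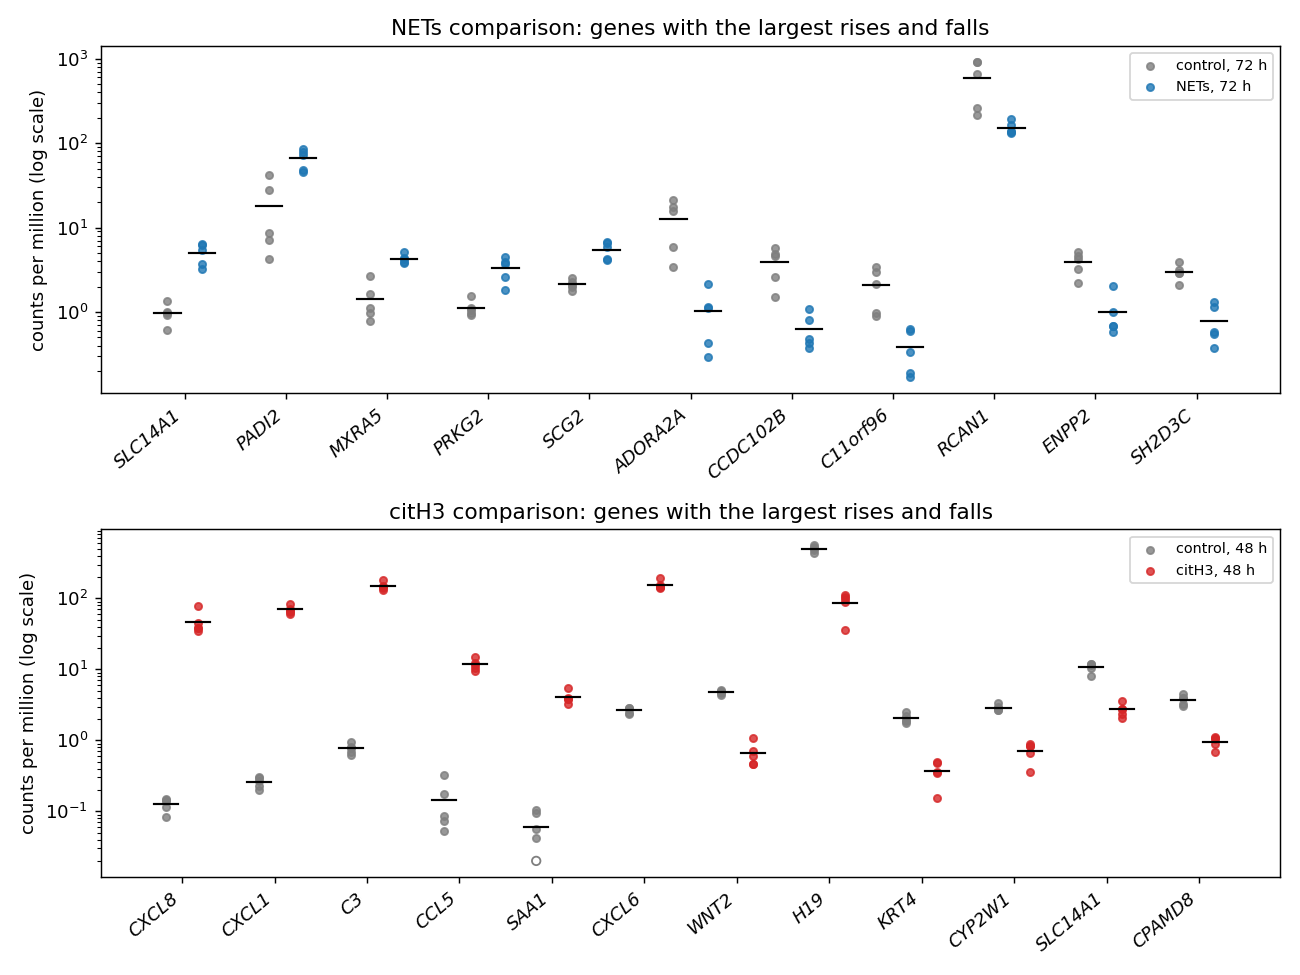
CPM (log scale) of leading genes with large rises and falls in each comparison, 1 dot per library, with grey dots for controls, coloured dots for stimulated libraries, black bars for group means and open circles at 0.02 for libraries with no count. CXCL8 stands at 0.126 in the 48 h controls and 47.0 CPM with citH3, and ADORA2A at 12.6 in the 72 h controls and 1.02 CPM with NETs.

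Of 21 cytokines and chemokines tested after citH3, 20 rose and 1 fell, also when adjusted over the list alone. CCL2, a monocyte chemokine, rose from 19.0 ± 2.19 to 262 ± 30.0 CPM and IL6 from 0.900 ± 0.155 to 17 ± 9.96 CPM, while CXCL12 fell from 542 ± 50.2 to 242 ± 26.3 CPM. For this list the camera adjusted p was 3.78e-19, and adjusted p = 0.0303 with an estimated correlation. All 20 genes of NF-kappaB feedback and adhesion rose, in both counts (20 adjusted over the list alone). SOD2, the mitochondrial superoxide dismutase, rose from 47.8 ± 1.70 to 608 ± 57.7 CPM, TNFAIP3, an inhibitor of NF-kappaB signalling, by 3.11 ± 0.07, VCAM1 by 2.71 ± 0.05 and ICAM1 by 2.15 ± 0.04. The camera adjusted p was 8.43e-26, and adjusted p = 0.00731 with an estimated correlation.

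Of 34 interferon-response genes tested, 33 rose and 0 fell (34 rose when adjusted over the list alone). IFI27 rose from 1.83 ± 0.236 to 28.8 ± 5.30 CPM, IFI6 from 31.1 ± 9.74 to 567 ± 91.0 CPM and OAS1, a sensor of double-stranded RNA, by 4.21 ± 0.34. MX1, an antiviral GTPase, rose by 3.94 ± 0.49, and by 4.91 without control 5. CXCL10 had 2 counts over the 5 controls and 555 over the 5 citH3 libraries, a ratio of 334 relative to total counts (92.0 to 2763, 95% exact interval, counting error only). The camera adjusted p of the list was 1.18e-25, and adjusted p = 0.0852 with an estimated correlation. Of 19 antigen presentation genes 17 rose and 1 fell, also when adjusted over the list alone. HLA-B rose from 500 ± 36.3 to 2307 ± 203 CPM and B2M, the light chain of class I molecules, by 1.13 ± 0.06. HLA genes share sequence, so their single values are uncertain. Camera gave the list an adjusted p of 2.23e-13, and adjusted p = 0.0391 with an estimated correlation. Of 17 innate receptors and inflammasome genes 9 rose and 2 fell (10 and 2 adjusted over the list alone). TLR1 rose by 2.89 ± 0.11, TLR3 by 2.18 ± 0.10, TLR2 by 1.6 ± 0.13 and TLR4, the receptor for endotoxin, by 0.53 ± 0.07. By camera the list had an adjusted p of 0.000567, and adjusted p = 0.085 with an estimated correlation. Of 21 complement and coagulation genes 10 rose and 8 fell, also when adjusted over the list alone, without a camera call. CFB, a factor of the alternative pathway, rose from 21.3 ± 0.781 to 115 ± 4.84 CPM, and C4A, which shares reads with its near-identical copy C4B and is uncertain, fell by 0.83 ± 0.09 on the log2 scale.

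**Figure D3:**
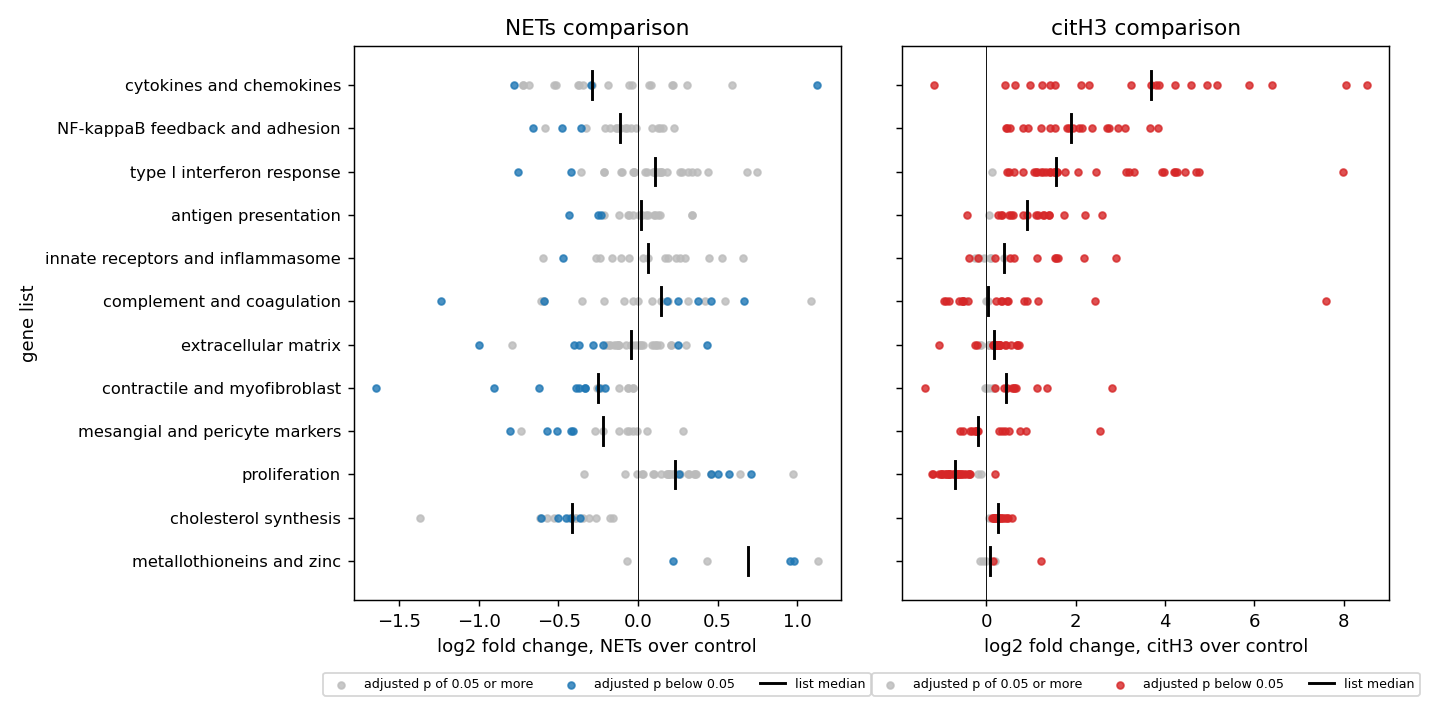
Log2 fold changes of the tested members of 12 gene lists after NETs (left) and citH3 (right), 1 dot per gene, grey where the edgeR adjusted p was 0.05 or more and coloured where it was below, with a black bar at the list median. The cytokine list has its median at -0.29 after NETs and 3.68 after citH3, and the proliferation list at 0.23 and -0.70.

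Proliferation genes were lower after citH3: 27 of 30 fell and 1 rose, also when adjusted over the list alone. TOP2A, a topoisomerase of dividing cells, fell from 21.1 ± 0.960 to 10.1 ± 0.807 CPM, and MKI67, the Ki-67 antigen, by 0.90 ± 0.09 on the log2 scale. For this list the camera adjusted p was 1.20e-17, and adjusted p = 0.0184 with an estimated correlation. Of 16 contractile genes 10 rose and 1 fell (12 and 1 adjusted over the list alone). MYOCD, a transcription factor of smooth muscle, rose from 27.8 ± 3.23 to 71.4 ± 4.26 CPM, MYH11 from 8.96 ± 2.71 to 62.2 ± 11.5 CPM and ACTA2 by 0.63 ± 0.08. The camera adjusted p was 7.22e-05, and adjusted p = 0.325 with an estimated correlation. Of 32 extracellular matrix genes 19 rose and 3 fell (21 and 4 adjusted over the list alone). COL8A1 (0.68 ± 0.05), the basement membrane collagen COL4A1 (0.69 ± 0.05) and the fibronectin gene FN1 (0.30 ± 0.07) rose, and the elastin gene ELN fell from 375 ± 80 to 180 ± 27.9 CPM. Camera gave the list an adjusted p of 7.22e-05, and adjusted p = 0.340 with an estimated correlation. Of 16 mesangial and pericyte markers 7 rose and 9 fell, also when adjusted over the list alone, among them RGS5 (0.89 ± 0.07) and PDGFRA (-0.58 ± 0.07); the list had no camera call.

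Of 18 cholesterol synthesis genes 16 rose and 0 fell (17 adjusted over the list alone). By camera the list had an adjusted p of 4.84e-07, and adjusted p = 0.143 with an estimated correlation. Of 15 p53 and cell death genes 9 rose and 1 fell (11 and 1 adjusted over the list alone), among them the death receptor gene FAS (0.86 ± 0.04) and the cell cycle inhibitor CDKN1A (0.61 ± 0.05). For this list the camera adjusted p was 7.27e-05, and adjusted p = 0.0852 with an estimated correlation. Of 18 genes of the unfolded protein and amino acid response 9 rose and 3 fell (10 and 3 adjusted over the list alone), led by PDIA4 (0.47 ± 0.06). The camera adjusted p was 0.0379, and adjusted p = 0.560 with an estimated correlation. That call was lost without control 1 (camera adjusted p = 0.0653), control 2 (0.0574) or citH3 5 (0.0625).

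The remaining lists had no camera call after citH3. Of 22 proteases and inhibitors 10 rose and 5 fell (12 and 7 adjusted over the list alone), among them the collagenase MMP13 (2.41 ± 0.22). Of 23 hypoxia and glycolysis genes 7 rose and 7 fell in both counts, 7 and 7 adjusted over the list alone, led by PFKP (0.34 ± 0.04). Of 15 NRF2 targets 6 rose and 1 fell (7 and 1 adjusted over the list alone), led by the ferritin chain FTH1 (0.89 ± 0.07); camera called this list without citH3 2 (adjusted p = 0.0330) or citH3 3 (0.0402). Of 6 metallothionein and zinc genes 2 rose and 0 fell, also when adjusted over the list alone, led by MT2A (1.23 ± 0.11). Of 17 immediate early genes 6 rose and 6 fell (6 and 7 adjusted over the list alone), led by EGR2 (1.43 ± 0.09). Of 16 TGF-beta targets 8 rose and 3 fell, also when adjusted over the list alone, led by BHLHE40 (0.82 ± 0.07). Of 13 mitochondrially encoded transcripts 3 rose and 0 fell (1 adjusted over the list alone), led by MT-ND5 (0.33 ± 0.09). The median and mean had opposite signs for the mesangial and immediate early lists, and the camera direction of the hypoxia list was opposite to its median.

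Summed neutrophil markers rose from 1.85 ± 0.306 to 48.7 ± 17 CPM after citH3, in a list that holds CXCL8, which had 0.129 and 45.8 CPM on the same library totals. Monocyte and macrophage markers rose from 4.55 ± 0.519 to 10.7 ± 1.88, tubular epithelial markers fell from 1484 ± 111 to 1013 ± 84.1 and olfactory receptor transcripts fell from 7.44 ± 0.419 to 5.53 ± 1.02 (each adjusted p = 0.0179, exact permutation test over 9 sums). The olfactory receptor sum, set as the check for genomic DNA, thus differed between the groups compared, and the cause was not tested. KRT18 made up most of the tubular fall, from 1351 to 905, and CD68 the largest part of the monocyte rise, from 2.32 to 5.94, on library totals. Podocyte markers rose from 753 ± 43.3 to 821 ± 25.5 (adjusted p = 0.0429, exact permutation test), a call lost without control 2, 3 or 4 or citH3 1, 2, 3 or 4 (ratio of citH3 to control 1.07 to 1.09). Endothelial (158 ± 9.99 and 147 ± 2.59), lymphocyte (12.5 ± 0.391 and 12.3 ± 1.01), erythroid and platelet (0.329 ± 0.138 and 0.196 ± 0.0730) and mitochondrial sums did not pass, and the endothelial sum passed without control 5 (ratio 0.911). By gene, 3 of 4 neutrophil and 3 of 4 monocyte markers tested rose, including CD14, a co-receptor for endotoxin (1.45 ± 0.12), and 1 of 3 lymphocyte markers rose (IL7R, 1.92 ± 0.15) and 1 fell. Of 10 endothelial markers 1 rose and 2 fell (EMCN, -1.21 ± 0.10), of 7 podocyte markers 2 rose and 3 fell (WT1, -1.02 ± 0.07), and of 9 tubular markers 0 rose and 4 fell (AQP1, a water channel, -1.57 ± 0.12). Adjusted over the list alone, 3 neutrophil, 3 monocyte, 1 lymphocyte, 1 endothelial, 2 podocyte and 1 tubular marker rose, and 1 lymphocyte, 1 endothelial, 3 podocyte and 4 tubular markers fell. The platelet gene ITGA2B, alone tested of its list, did not pass in either count (-0.82 ± 0.39).

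The responses to both stimuli were then set side by side. Genes that moved in opposite directions included SLC14A1 (2.36 after NETs, -1.99 after citH3), PADI2 (1.89 and -1.37), CXCL12 (1.12 and -1.17), MYH11 (-1.65 and 2.80), ACTA2 (-0.34 and 0.63) and ICAM1 (-0.48 and 2.15), all log2 fold changes past the edgeR threshold. The controls of the 2 durations did not start at like levels. In the fit of all 20 libraries SLC14A1 stood at 0.992 CPM in the 72 h controls and 10.6 in the 48 h controls, and PADI2 at 18.3 and 11.7. The calls of PADI2 and MYH11 after NETs were lost in fits without single libraries, as given above. Of 17457 genes tested in both comparisons, 956 were called in both, 341 in the same direction and 615 in opposite directions. Independent lists would share 320 and 331. Genes lower after NETs and higher after citH3 numbered 439 against 230 for independent lists (two-sided Fisher's exact p = 3.30e-48), and genes higher after NETs and lower after citH3 numbered 176 against 101 (two-sided Fisher's exact p = 1.87e-14). The genes higher in both numbered 113 against 111 (exact p = 0.873) and those lower in both 228 against 208 (exact p = 0.126). Genes are not independent replicates, so these p-values are too small. The Spearman correlation of the fold changes across genes was -0.07 over all 17457 genes and -0.21 over the 956. The comparisons share no control library. Leaving out libraries moved the counts by more than 1.5 times, with 156 to 802 genes in the same and 292 to 1172 in opposite directions, the highest without 72 h control 4.

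**Figure D4:**
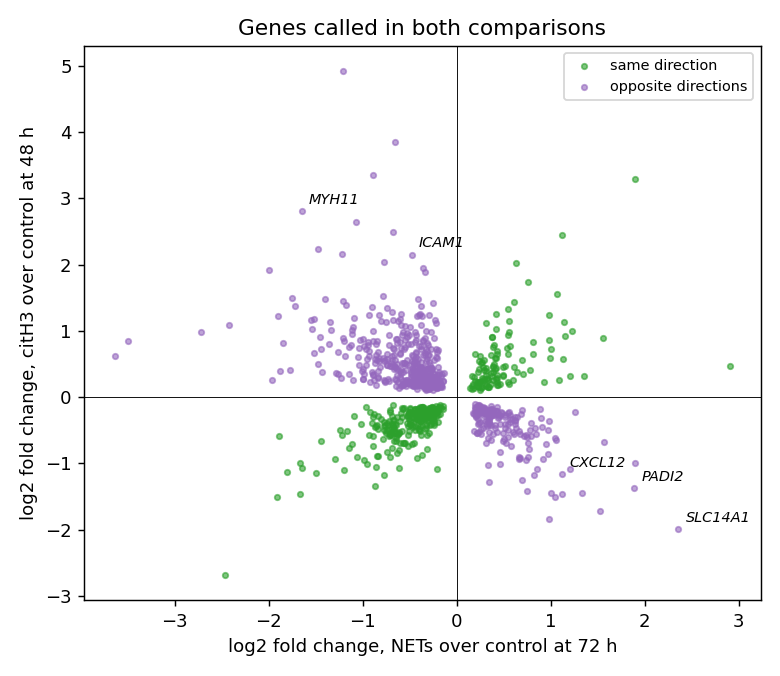
Log2 fold changes after NETs (x axis) and after citH3 (y axis) of the genes called in both comparisons, 1 dot per gene, green for the same direction and purple for opposite directions; Y-linked genes and genes of X inactivation are not drawn. More genes lie in the upper left (439) and lower right (176) than in the lower left (228) and upper right (113).

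The difference of the effects, NETs minus citH3, was tested over all 20 libraries. Among genes with a symbol at 2 CPM or more in at least 1 group it was largest for SLC14A1 (4.35 ± 0.29), OGN, a small proteoglycan (4.08 ± 0.57), PADI2 (3.26 ± 0.59), CBLN2 (2.89 ± 0.26) and SLC7A14 (2.78 ± 0.36), and most negative for CXCL8 (-8.85 ± 0.40), CXCL1 (-8.42 ± 0.30), C3 (-7.04 ± 0.21), CXCL6 (-6.59 ± 0.28) and CCL5 (-6.17 ± 0.52). OGN stood at 0.0223 CPM in the 72 h controls and at 26.0 CPM in the 48 h controls, so its effect after NETs rests on few counts. Of 19513 genes tested, 5128 differed by the edgeR test, with 2364 above and 2764 below 0. The effect of NETs lay below that of citH3 in 21 of 23 cytokines and chemokines, 19 of 20 NF-kappaB genes, 30 of 34 interferon-response genes, 14 of 19 antigen presentation genes, 12 of 16 contractile genes and 12 of 18 cholesterol genes. It lay above in 26 of 30 proliferation genes. With library totals in place of trimmed-mean factors the split of the calls was 4101 above and 1940 below 0. Stimulus, amount, duration and table differed together in this contrast, so it does not separate them.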

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

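The tests of a single wrong label, of RNA carried by the NETs, of transcription by the cells, of endotoxin, and all other splits of the libraries except those for the overlap counts were chosen after the results they bear on were seen. In the test of exchanged labels, the demand that a position lie beyond the spread of the NETs libraries was also added after the value was seen, as were the demand in the test of culture state that its sides share no library and the reading that splits without calls decide nothing about overlaps.

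The 72 h libraries did not separate cleanly by label. Each library was placed on its own axis, over the genes called without it. There 0 was the mean of the controls and 1 that of the NETs libraries, with the placed library left out. Control 4 lay at 0.688 and control 2 at 0.412, NETs 1 and NETs 2 at 0.626 and the other NETs libraries between 1.08 and 1.16. Exchanging the labels of control 4 and NETs 1 gave 3711 called genes in place of 1980, while the other 24 single exchanges gave 0 to 240. An exchange of these libraries would put NETs 1 on the control side of the axis drawn from the other 8. It lay at 0.610, on the NETs side by less than the SD of the NETs libraries on their own axes (0.265). That SD comes from other axes and is only a rough guide, and the exchange cannot be told apart. A single wrong label on control 4 cannot be told apart either, since its position of 0.688 lay within the range of the NETs libraries (0.626 to 1.16). A culture state that varies between wells along the same genes cannot be told apart: across genes, the first component of controls 1, 2, 3 and 5 had a Spearman correlation of 0.475 with the NETs fold changes taken without control 4 and NETs 1, but the same controls enter both sides. At 48 h, where the controls also enter both sides, the correlation with the citH3 fold changes was 0.0971. The effect of NETs itself is the biological explanation that the design names, and it stays open beside these.

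Transcripts of myeloid precursors (11 genes, 6 of them also in the neutrophil or monocyte list) appeared in all 72 h libraries, at 3.65 ± 0.239 CPM in controls and 3.87 ± 0.399 with NETs, led by MPO, the gene of myeloperoxidase (2.10 ± 0.124 in controls), against 0.202 ± 0.0929 in the 48 h controls. RNA carried into the wells with the NETs would raise the NETs libraries over the controls, and the ratio was 1.06 ± 0.0578 (standard error), which argues against it as the source. Transcription by the mesangial cells at any time in culture would need a like level at 48 h. The 48 h controls stood at 0.0552 of the 72 h controls, which argues against a like level at both times. The values come from 2 tables made separately, and OGN also differed between their controls, at 26.0 CPM at 48 h and 0.0223 at 72 h. The gap therefore does not decide against transcription by the 72 h cells. Of the 11 genes 8 are listed at 48 h, so that sum covers fewer genes. MPO, listed at both times, stood at 0.0582 CPM in the 48 h controls. Transcription that starts after 48 h, or in another lot of cells, was not tested. Reads or RNA of another sample spread over the 72 h libraries could account for the even level: the sum varied less between libraries than most genes of like count (percentile 7.45), which lies between the bounds set for and against it and decides nothing.

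The inflammatory and interferon genes that rose after citH3 were weighed against 2 technical explanations. A single strongly responding library was excluded, since without any 1 citH3 library the list medians stayed at 0.926 or more of their values. Endotoxin in the recombinant protein could not be told apart from citH3, as the cells express the receptor TLR4 (28.4 ± 1.99 CPM in the 48 h controls) and its partner LY96 (3.62 ± 0.443), and no protein control is among the groups. The effect of citH3, which the design names, stays open.

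The libraries were also regrouped into 100 splits of the same sizes, the real one included. For the NETs comparison 2 of 100 splits gave 1980 genes or more. They were the real split and that with control 4 and NETs 1 exchanged, at 3711, which points to a structure of the samples. Such a count was rare among the splits. The splits cannot tell an effect of NETs from a culture state or a wrong label that falls along the same libraries. Chance can be excluded for citH3 (5997 genes, highest other 1, 1 of 100). For the difference of effects only the real split gave as many (5128, highest other 715, 1 of 100). The other splits regrouped both tables at once and so also broke up the citH3 effect. They cannot tell a difference between the effects from an effect of citH3 alone. For the genes called in both comparisons, 341 in the same and 615 in opposite directions, the splits decide nothing: 97 of the others called no gene after NETs and 98 none after citH3, so their overlap (highest other 0) is fixed beforehand. The splits do not exclude chance for the number of lists that camera called with a preset correlation. That number was 6 after NETs (highest other 12, with 30 of 100 splits giving as many) and 11 after citH3 (highest other 14, 14 of 100). After citH3 the splits with 14 lists kept 4 controls in the same group and so still held much of the real contrast. They therefore do not show that the 11 lists came by chance. For the 4 lists called after citH3 with an estimated correlation only the real split gave as many (highest other 0, 1 of 100). The other splits leave the citH3 effect within the groups, where it enters the estimated correlation. Their 0 therefore does not exclude chance for these lists apart from the effect over all genes.

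A library far from the others of its group was found in 30 of 274 groups of values tested (10.9%), where chance gives about 1 in 20. In CPM, citH3 4 stood apart in CXCL8 (77.4), CXCL6 (193), IL6 (34.7), SOD2 (709), TNFAIP3 (214), PDIA4 (307), BHLHE40 (74.1), IL7R (5.11) and MMP13 (7.52), each the highest, and in RGS5 (187) and MYH11 (42.3), each the lowest. Its sums of neutrophil (78.4) and monocyte and macrophage markers (14 CPM) were the highest as well. The 48 h control 5 stood highest in MX1 (21.1), IFI6 (47.9) and ELN (515), and control 1 in the share of its 20 most abundant genes (24.5%). At 72 h, NETs 2 stood highest in ENPP2 (2.06), LAMA4 (40.2), NOTCH3 (460) and TFPI (67.7), NETs 1 in ANKRD37 (17.2) and MYH11 (21.9), and NETs 5 lowest in the monocyte and macrophage sum (3.32). Control 1 stood lowest in NLRP1 (65.0), ACTA2 (4458) and IL6 (2.71) and highest in the tubular sum (2185), and control 2 stood highest in MX1 (16.8).

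The effects of the stimuli differed by the test of the difference in 5128 genes. Of the genes with a symbol among them at 2 CPM or more in at least 1 group, SLC14A1 (4.35), OGN (4.08), PADI2 (3.26), CBLN2 (2.89) and SLC7A14 (2.78) had the largest positive log2 difference, NETs minus citH3, and CXCL8 (-8.85), CXCL1 (-8.42), C3 (-7.04), CXCL6 (-6.59) and CCL5 (-6.17) the most negative.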

How the results depend on the processing

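Voom with quality weights, the TMM-adjusted totals of the marker sums, the left-out libraries for those sums and all settings for genes called in opposite directions were chosen after the data were seen. After NETs the main test called 1980 genes, DESeq2 3433, the fit of all 20 libraries 3997 and voom with quality weights 7576; the first 2 kept 1944 and 1945 of the 1980 and the last all of them, in the same directions. Leaving out 1 library gave 809 to 4692 genes: 4692 without control 4, and 809 without control 3, 839 without control 5, 824 without NETs 3, 891 without NETs 4 and 837 without NETs 5. Control 4 had the lowest quality weight, 0.310. Voom with quality weights moved the log2 fold changes after NETs of PADI2 from 1.89 to 2.92, ADORA2A from -3.63 to -4.22, C11orf96 from -2.43 to -3.14 and MYH11 from -1.65 to -2.32, and after citH3 of MX1 from 3.94 to 4.59 and CXCL10 from 7.98 to 7.01 (7.38 with voom alone), each by more than 1.5 times in fold. The counts for citH3 (5306 to 6069 with 1 library left out) and for the difference of effects (4423 to 6251) stayed within 1.5 times under every setting run. With library totals only, the median log2 difference of effects over all genes moved from 0.01 to 0.11. The median log2 fold change over all genes moved from 0.0024 to 0.0395 after NETs and from -0.0097 to -0.0814 after citH3. The split of the calls also turned: after NETs from 646 higher and 1334 lower to 1526 and 978, after citH3 from 3139 and 2858 to 2113 and 4455, and in the difference from 2364 above and 2764 below 0 to 4101 and 1940. Each split turned in the direction in which its median moved. No gene named as called and no list called by camera changed its direction under the settings run for it. Genes that did not pass changed sign: after NETs MX1 (-0.10; 0.54 with quality weights, 0.39 with the replicate block, 0.33 with voom alone, 1.12 without control 2), ITGA2B and COL1A1 in some settings, none of them passing. The cause was not tested for any of these changes.

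Genes called in the same direction numbered 614 with DESeq2 and 89 at adjusted p below 0.01, and 156 to 802 with 1 library left out; those in opposite directions numbered 987, 150 and 292 to 1172. Both were lowest or highest without the 72 h libraries named above: without control 3 they were 157 and 293, without control 4 802 and 1172, without control 5 162 and 304, without NETs 3 157 and 292, without NETs 4 165 and 322, and without NETs 5 156 and 304. In the settings run the opposite count was 1.53 to 2.73 times that of independent lists and the same-direction count 0.933 to 1.73 times, both highest at adjusted p below 0.01, where independent lists would share 54.9 and 51.6. Camera called 6 lists after NETs, 0 with an estimated correlation, 8 with fry and 5 to 7 with 1 library left out. Fry did not call the proliferation list (fry adjusted p = 0.131) or the cholesterol list (fry adjusted p = 0.0936) after NETs. It called the cytokine, complement, neutrophil and podocyte lists, which camera did not. After citH3 camera called 11, 4 with an estimated correlation, 18 with fry, which does not compare a list with other genes, and 10 to 13 with 1 library left out. The list of metallothioneins after NETs was lost with the filter at 1 CPM in 5 libraries (adjusted p = 0.0623), and the cause was not tested.

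With the replicate number as a replicate block 3101 genes were called after NETs, 5338 after citH3 and 5230 in the difference. The labels tie the numbers to no shared culture or day. The correlations of deviations of same-numbered libraries were 0.23, 0.11, -0.06, 0.19 and -0.02 at 72 h and -0.01, 0.01, -0.12, 0.03 and 0.07 at 48 h, and libraries did not all correlate best with their own number; at 72 h those numbered 1, 2 and 4 did in both groups, those numbered 3 and 5 in neither, so the numbers were not taken to pair the samples.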

Other observations

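The gene groups in this part were chosen after the values were seen, and none of their counts was recomputed under the alternatives. Of 13 ligands, receptors and targets of the Notch pathway, a contact-dependent signalling route between neighbouring cells, 9 fell and 0 rose after NETs, with a median log2 fold change of -0.86; of all 18319 genes tested 1334 fell. The group has no test of its own, since it was chosen for these values. NOTCH3, the receptor of mural cells, went from 547 ± 86.4 to 314 ± 84.4 CPM (-0.80 ± 0.16) and the ligand JAG1 from 504 ± 100 to 256 ± 61.7 (-0.97 ± 0.17). The targets HES1 (-0.48 ± 0.10), HEY1 (-1.72 ± 0.36), HES4 (-0.91 ± 0.22) and NRARP (-0.86 ± 0.20) were also lower, HEYL fell from 3.34 ± 1.74 to 0.722 ± 0.863 CPM, and NOTCH2 did not pass (0.20 ± 0.13). After citH3, 4 of 12 tested rose and 2 fell. Among these DLL4 (2.19 ± 0.24), NOTCH2 (0.79 ± 0.08) and HEY1 (1.38 ± 0.17) were higher and JAG2 (-0.82 ± 0.10) and NOTCH3 (-0.32 ± 0.07) were lower.

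Chemokine genes that lie side by side on chromosome 4, from CXCL8 at 73740506 to CXCL2, which ends at 74099293, moved together after citH3. All 6 that could be tested rose, with CXCL5 at 5.16 ± 0.12, CXCL3 at 4.94 ± 0.27 and CXCL2 at 4.58 ± 0.22, while PF4, in the same stretch, had 17 counts over the 5 controls and 16 over the 5 citH3 libraries. After NETs 0 of 5 tested passed. On chromosome 9 the small proteoglycan genes OGN (-1.97 ± 0.12), ASPN (-1.82 ± 0.16) and OMD (-1.42 ± 0.16) fell after citH3, and their neighbour ECM2 did not pass (-0.13 ± 0.09). In the fit of all 20 libraries OGN stood at 26.0 ± 2.46 CPM in the 48 h controls and at 0.0223 ± 0.00924 in the 72 h controls, in tables that were made separately.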
